A study of Canis lupus familiaris with 6 samples.

How the data were processed

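Single-cell RNA was measured in 6 libraries of dog neural retina: in each of 3 independent experiments, 1 punch of 5 mm lying over a graft of human retinal organoid fragments and 1 punch of 5 mm from a graft-free area of the same retina, taken 3 days after grafting. Per the labels' protocols, tissue was digested for 10 min in trypsin (0.25%), dissociated and loaded for 3' single-cell libraries. Every library was mapped to its group and experiment from its label, and 0 columns stayed unmapped.

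The deposited values are raw UMI counts per gene and barcode, made with Cell Ranger 6.0.2 for both LG5 libraries, 7.1.0 for the RC726 punch over the graft, 7.0.0 for the RC726 control and 7.1.0 for both RC724 libraries, per the file headers. The barcode lists are filtered: no barcode has fewer than 500 UMIs. The genome build, the annotation and the handling of intron reads are not given in the sources used here, nor is whether human reads from the graft were separated, so no statement on graft cells is made. Of 34981 gene names in the files, 33363 match a symbol in the RefSeq table of the dog assembly UU_Cfam_GSD_1.0 and 1618 do not. Within LG5 and RC724 both punches share a software version, so the block for the experiment takes up version differences between experiments. It does not take up the difference between the RC726 punches.

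Barcodes with at least 300 genes and at most 20% of UMIs from 13 mitochondrial genes were kept. Scrublet's automatic threshold called at most 0.035% of the barcodes of a library doublets, so the 6% with the highest doublet score were removed from each library, a choice made after the data were seen. This left 22458 and 16844 barcodes in LG5, 10640 and 9314 in RC726, and 8701 and 8079 in RC724 (over the graft, control). The median percent of mitochondrial UMIs of kept barcodes was 3.55% and 5.62% in LG5, 4.66% and 3.10% in RC726, and 5.296% and 4.22% in RC724 (over the graft, control), so it was lower over the graft in LG5 and higher in RC726 and RC724.

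Clusters were computed over all libraries with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and leidenalg 0.10.2 under Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9). Genes variable in the control libraries were joined with the marker genes, and 422 genes that differed between the punches were left out unless they were markers, which gave 2505 genes, each scaled within its library. From these, 30 principal components, 20 neighbours and a Leiden resolution of 1.5 gave clusters, and 1593 barcodes in immune clusters were clustered again on their own, for 67 clusters in all. A cluster was named after the marker list, of 20 written before the data were examined, with the highest mean log2 enrichment, computed with a pseudocount of 20 CPM. A name needed a score of at least 1.2, a margin of 0.5 over the next list, at least 3 markers and at most 30% of barcodes called doublets, and no other list with more markers among the top 10 genes of the cluster. These limits were set after the data were seen. By this rule 46 clusters were named, and classes are written as rod-like, cone-like and so on because no sort or label gives them. Clusters separated LG5 from RC726 and RC724.

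UMIs were summed per library and class. A class was tested where all 6 libraries held at least 20 cells of it. The test was edgeR 4.0.16 (quasi-likelihood, filterByExpr by group, TMM) in R 4.3.3, with the experiment as a block and the group as the tested term, and adjustment by Benjamini-Hochberg at 0.05. The SE of a log2 change is its size divided by the square root of the F statistic, and is left out where F is near 0. Log2 ratios per experiment are computed on CPM + 1. The difference between Müller glia-like and rod-like changes was tested as an interaction in 1 edgeR fit of 12 sums, with a term per library. Shares were compared by an exact paired sign-flip test on the log2 ratio, whose smallest p with 3 pairs is 0.25 (0.1 unpaired). For 31 gene lists fixed before the data were examined, camera in limma 3.58.1 was run with a preset correlation of 0.01 on lists with at least 3 tested members and adjusted within each class.

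The text names, per class, genes with an adjusted p under 0.05, one direction in all 3 experiments, a symbol and a mean of at least 20 CPM in the higher group: the 8 largest rises and the 8 largest falls, and up to 4 members past the threshold of each list by p. Where fewer than 8 genes pass, the 5 with the smallest p are given as values. GFAP, VIM, GLUL, RLBP1, AQP4, STAT3 and SOCS3 in Müller glia, GNAT1, SAG and CRX in rods, ARR3 in cones, and CX3CR1, P2RY12, AIF1, CD74, C1QA and SPP1 in microglia are given in every case. Of the genes this rule allows, the text names a part. Lists are those with the smallest camera p in a class or those that a gene named beside them belongs to.

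Pairing comes from the design, in which both punches of an experiment are from the same retina. It was checked by the correlation of the deviations of paired sums from their group means. This was between 0.419 and 0.965 in the classes with 20 cells in every library and in the whole punch, and 0.185, 0.227 and -0.082 in microglia- or macrophage-like cells. The highest correlation with another experiment was 0.812 for RC726 and 0.825 for RC724 in rods, against 0.914 and 0.943 within the pair, and in amacrine cells of RC726 it was 0.479, above the 0.419 within the pair.

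The tests were run on simulated data made from the real means, with 200 genes changed. edgeR recovered 77.6% of genes changed by a log2 of 1 in rods, 60.2% in Müller glia, 84.8% in cones, 71.0% in bipolar, 67.4% in amacrine and 71.0% in horizontal cells, 4.55% in microglia and 68.7% in the whole punch. False calls made up 16.3%, 14.0%, 7.29%, 12.5%, 3.16%, 7.47%, 0% and 22.1% of its calls in the same order. In rods, Müller glia, cones, bipolar and horizontal cells and the whole punch this exceeded the nominal 5 in 100. The real counts there may also hold more false calls than that. Their false share was not estimated, as it depends on how many genes truly change, which was set to 200 here. The interaction fit with a term per library recovered 0% of simulated genes at a log2 of 2, and 89.3% once a class-by-experiment term was added. Camera called 0 of 30 random lists in each simulated comparison. Genes were drawn independently in the simulation, so it cannot show how often camera calls lists of correlated genes. In the real rod sums the estimated correlation was 0.825 for the interferon list and 0.884 for the rod phototransduction list.

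Alternatives chosen before the data were examined were the fit without the block, DESeq2 1.42.0, RLE size factors, no filter on low counts, a stricter filter on barcodes (500 genes, 10% mitochondrial UMIs), doublets kept, sums thinned to the lowest total, each experiment left out in turn, and subtraction of free RNA estimated from rod marker genes. For lists they were camera with an estimated correlation and fry. The profile subtracted as free RNA was the sum over all kept barcodes of a library, not that of empty droplets, so it also held RNA of the class itself. Chosen after the data were seen were the fit of microglia- or macrophage-like cells without the minimum of 20 cells, the rod fit without clusters lacking a rod marker in their top 10 genes, the alternatives of horizontal-like cells, and the class-by-experiment term. Ganglion-like, astrocyte-like, endothelial-like and T or NK cell-like barcodes fell under 20 in at least 1 library and were not tested for genes.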

Results

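Neural retina of immunosuppressed dogs with normal retinas was profiled by single-cell RNA sequencing 3 days after fragments of human retinal organoids had been placed under it. The organoids came from WA09, an established human embryonic stem cell line that here carried a CRX-tdTomato reporter. In each of 3 independent experiments, named LG5, RC726 and RC724, a 5 mm punch of retina lying over the graft and a 5 mm punch from an area without graft (control) were dissociated, which gave 6 libraries, 3 per group. The comparisons ask how the cells of the host retina differ between the area over a graft and an area away from it.

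In LG5, 23908 barcodes with 46008764 UMIs were deposited for the punch over the graft and 18300 barcodes with 34768162 UMIs for the control. The RC726 libraries held 12695 barcodes with 53691864 UMIs over the graft and 10989 barcodes with 39678572 UMIs in control. The RC724 libraries held 9747 barcodes with 60755006 UMIs over the graft and 8778 barcodes with 51689236 UMIs in control. After filtering, between 8079 and 22458 barcodes per library remained, with medians between 1196 and 2780 UMIs per barcode. Whether each experiment used a separate dog is not given in the sources used here. With the experiment as a block, the edgeR p-values measure how the difference between punches varies between experiments, and no spread between dogs is claimed. Each gene had 2 residual degrees of freedom, and its spread was drawn toward that of other genes. The prior degrees of freedom were 9.1 in rods, 66.5 in amacrine cells and infinite in microglia.

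Rod-like cells made up between 64.8% and 72.5% of the retained barcodes in RC726 and RC724 and 21.7% and 28.2% in LG5 (over the graft and control), and microglia or macrophages took a larger share over the graft than in control in each of the 3 experiments. Rod-like cells averaged 52.1% ± 26.3 (SD, n = 3) of barcodes over the graft and 55.2% ± 23.7 (SD, n = 3) in control. Müller glia-like cells, the radial glia of the retina, averaged 18.3% ± 3.36 and 17.8% ± 7.98, and bipolar-like interneurons 12.99% ± 10.3 and 13.2% ± 6.74. Microglia- or macrophage-like cells averaged 1.08% ± 1.33 over the graft and 0.478% ± 0.564 in control. Their log2 ratios were 1.21 in LG5, 1.01 in RC726 and 1.03 in RC724 (mean 1.08, SD 0.11, n = 3 pairs). Under the stricter barcode filter these ratios were 1.16, 0.84 and 2.89 (mean 1.63, SD 1.10), the last from 14 and 2 barcodes. An exact paired sign-flip test, two-sided, gave p = 0.25 for this class, which is the smallest p that 3 pairs allow, so no share could pass a threshold of 0.05. Endothelial-like cells had a mean log2 ratio of 0.82 (SD 0.36) and amacrine-like cells 0.57 (SD 0.49), each with an exact p of 0.25, and the smallest adjusted p over the classes was 0.75. Rod-like, cone-like and bipolar-like cells had mean log2 ratios of -0.14, -0.23 and -0.16, each smaller than its SD between experiments. The counts behind the microglia- or macrophage-like shares were 588 and 190 barcodes in LG5, 39 and 17 in RC726, and 22 and 10 in RC724, over the graft and in control. All shares depend on the names given here to clusters, and 16.4% and 14.1% of the LG5 barcodes and between 2.42% and 2.56% of the RC726 and RC724 barcodes stayed unnamed.

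Rod-like cells over the graft carried interferon-response transcripts that were close to missing from rod-like cells of the control punches. MX1, a GTPase that restricts viruses, averaged 170 CPM over the graft and 1.49 CPM in control, a log2 change of 6.16 ± 0.37 (SE, n = 3 pairs). IRF7, a transcription factor that drives interferon genes, rose by 5.98 ± 0.47, and ISG15, a ubiquitin-like modifier induced by interferon, by 5.62 ± 0.61. IFI44L, IFIH1 (an intracellular sensor of viral RNA) and OAS1 (which makes the activator of RNase L) rose by 6.30, 5.37 and 5.47, with SE between 0.33 and 0.37. The interferon-inducible GTPases IFGGB2 and IFGGC1 rose by 6.51 ± 0.50 and 6.07 ± 0.41. VMO1, a homologue of an egg membrane protein, reached 1960 CPM over the graft from 25.9 CPM in control (5.92 ± 0.61). Of 27 tested genes in the type I interferon list, 23 rose and 1 fell, or 24 and 1 when adjusted over the list alone, with a median log2 change of 4.39. The member that fell was IFI6, at -1.59 ± 0.23. It had 163 UMIs in rod-like cells over the graft and 402 in control, against 15265 and 30947 in Müller glia-like cells, where it also fell. Glial RNA in rod droplets was not tested as the source of this fall. The camera test gave the list an adjusted p = 1.84e-13, and adjusted p = 0.46 with an estimated correlation.

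MHC class I genes rose with them in the rod-like cells. B2M, the light chain of MHC class I, went from 2.75 to 57.9 CPM (4.08 ± 0.29, SE, n = 3 pairs). TAP1, which carries peptides to MHC class I, rose by 5.73 ± 0.36, and the class I heavy chain genes DLA-64 and DLA-12 by 2.89 ± 0.14 and 3.001 ± 0.22. DLA genes are close relatives, so a UMI of one can be counted for another. All 14 tested members of the MHC class I list rose, over all genes and adjusted over the list alone, with a median of 3.48 (camera adjusted p = 9.62e-12, and adjusted p = 0.46 with an estimated correlation). For MX1 the log2 ratio was 7.23 in LG5, 4.30 in RC726 and 5.47 in RC724, so every experiment showed the rise, at different sizes.

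Transcripts of the light response were lower in rod-like cells over the graft. GUCA1A, an activator of retinal guanylate cyclase, went from 1076 to 402 CPM, a fall of -1.40 ± 0.18 on the log2 scale (SE, n = 3 pairs, edgeR adjusted p = 0.000357). SLC24A1, the rod cation exchanger, fell by 1.35 ± 0.20. PDE6B, a catalytic subunit of the rod phosphodiesterase, fell by 1.0003 ± 0.14, and GUCY2F, a retinal guanylate cyclase, by 1.05 ± 0.14. Of the 20 genes of the rod phototransduction list, 16 fell (19 when adjusted over the list alone) and all 20 had negative values, with a median of -0.84 (camera adjusted p = 3.36e-09, and adjusted p = 0.46 with an estimated correlation). GNAT1, the rod transducin, had a log2 change of -0.45 ± 0.15 (edgeR adjusted p = 0.0524), SAG, the rod arrestin, -0.40 ± 0.17 (0.126), and CRX, a transcription factor of photoreceptors, -0.30 ± 0.13 (0.119). Among genes of the retinoid cycle and outer segment, RDH8 fell by 1.33, ABCA4 by 0.89 and RPGRIP1 by 1.504. Of 13 tested retinoid cycle genes 1 rose and 4 fell, or 1 and 5 over the list alone. Of 18 outer segment genes 3 rose and 6 fell, or 3 and 8 over the list alone. NR2E3, one of the rod marker genes, fell by 0.86. IMPG2, a proteoglycan of the matrix around photoreceptors, rose by 0.92 ± 0.16, and CPLX3, a complexin of ribbon synapses, by 1.499 ± 0.16. Of 18 genes of the ribbon synapse list 3 rose and 5 fell, or 4 and 6 over the list alone, 14 had negative values, and camera did not call it (adjusted p = 0.0907, and adjusted p = 0.544 with an estimated correlation). In the whole punch, rod marker genes held a smaller share of UMIs over the graft, at 0.539% against 1.27% in LG5, 0.726% against 1.03% in RC726 and 0.35% against 0.541% in RC724. This share also depends on the share of rod-like barcodes, which was lower over the graft in LG5 and RC726 and higher in RC724. The markers include GNAT1, PDE6B and SAG, so these values are no separate evidence for a fall within rods.

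**Figure D1:**
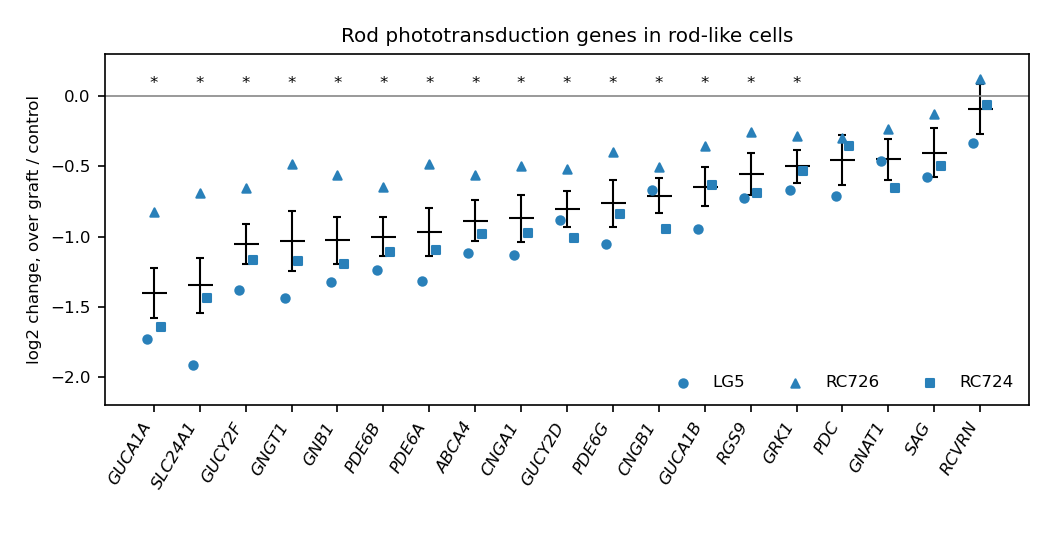
Log2 change (punch over the graft over control) of 19 of the 20 rod phototransduction genes in rod-like cells. Points are the 3 experiments (log2 ratio of CPM + 1), black bars the fitted change with its SE, and stars mark the 15 genes shown with an adjusted p under 0.05. RC726 points lie closest to 0 for most genes, and GUCA1A lies at -1.73 in LG5, -0.82 in RC726 and -1.64 in RC724.

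In the same rod-like cells, genes of the oxidative stress and metal list rose. HSP90AA1, a chaperone, rose from 3452 to 12682 CPM (1.79 ± 0.23, SE, n = 3 pairs), while the heat shock list had 3 of 13 genes rising and 0 falling, or 3 and 1 over the list alone, and was not called (camera adjusted p = 0.1285, and adjusted p = 0.544 with an estimated correlation). MT2A, a metallothionein, rose by 1.55 ± 0.16, PRDX1, a peroxide-reducing enzyme, by 1.17 ± 0.14, and FTL, the ferritin light chain, by 1.26 ± 0.15. Of 17 tested genes in the oxidative stress and metal list, 12 rose and 1 fell, or 13 and 1 when adjusted over the list alone (camera adjusted p = 0.000226, and adjusted p = 0.46 with an estimated correlation). STAT3 and IL6ST, a transcription factor and a receptor chain of interleukin-6 family signalling, rose by 1.26 ± 0.17 and 1.37 ± 0.15. NFKBIA and BCL3, regulators of NF-kB, rose by 1.11 ± 0.12 and 3.65 ± 0.27, and JUNB, an immediate early gene, by 1.34 ± 0.14. The largest falls under the naming rule included PLPPR2 (-2.37 ± 0.19), the secretory phospholipase receptor PLA2R1 (-2.21 ± 0.28), CFAP58 (-1.96 ± 0.18), the taurine transporter SLC6A6 (-1.79 ± 0.17) and NXNL1, which encodes rod-derived cone viability factor (-1.70 ± 0.14). The cytosolic ribosome list had 16 of 55 genes rising and 1 falling (22 and 1 adjusted over the list alone) with a median of 0.27 (camera adjusted p = 5.15e-06, and adjusted p = 0.46 with an estimated correlation).

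In all, edgeR with the experiment as a block called 3184 of 15247 tested genes in rod-like cells, 1646 higher and 1538 lower over the graft, and 2946 of them had one direction in all 3 experiments. Without the block, edgeR called 0 genes, with 671 at an unadjusted p under 0.05. Without the RC724 pair the count was 997.

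Müller glia-like cells over the graft had far less RNA of ALDH1A1 than those of the control punches, and more of THY1, L1CAM, FABP5 and NES. THY1, a surface glycoprotein, rose by 3.19 ± 0.31 on the log2 scale (SE, n = 3 pairs, edgeR adjusted p = 0.0257), and L1CAM, a neural adhesion molecule, by 2.98 ± 0.29. FABP5, a fatty acid binding protein, went from 24.9 to 140 CPM (2.01 ± 0.25), HK2, a hexokinase, rose by 1.75 ± 0.21 and NES, the intermediate filament nestin, by 1.51 ± 0.13. After subtraction of free RNA the log2 changes of FABP5, THY1 and L1CAM were 0.55, 1.86 and 6.17, with adjusted p = 0.665, 0.575 and 0.339. Over the alternatives that tested them, NES stayed between 1.40 and 1.61, HK2 between 1.48 and 2.11 and ALDH1A1 between -5.70 and -4.38. Their calls were not kept in all of these. SHISA9, PCLAF and PTHLH rose by 1.54, 1.54 and 1.34. ALDH1A1, which makes retinoic acid, fell from 80.8 to 2.20 CPM (-5.14 ± 0.42, edgeR adjusted p = 0.0211), with log2 ratios of -3.74 in LG5, -4.14 in RC726 and -5.78 in RC724. IFI6, an interferon-inducible gene, fell by 1.44 ± 0.15, CSMD3 by 1.86 ± 0.21, PDE5A, a cyclic GMP phosphodiesterase, by 1.19 ± 0.12, and H2AC20 and PMFBP1 by 1.45 and 1.17. The barcodes of this class were split unevenly between clusters. In LG5, cluster 11 held 564 barcodes over the graft and 1368 in control and cluster 1 held 3990 and 2889, and in RC726, cluster 23, with IFI6 among its top 10 genes, held 352 and 331 while cluster 8 held 791 and 446.

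GFAP, the intermediate filament used as a marker of glial reaction, was at 161 CPM over the graft and 32.9 CPM in control in Müller glia-like cells, a log2 change of 2.21 ± 0.38 (SE, n = 3 pairs) with an edgeR adjusted p = 0.0773. VIM, another filament, had a change of 0.29 ± 0.25 (adjusted p = 0.701). The glutamine synthetase gene GLUL had -0.79 ± 0.40 (0.492), the retinoid carrier RLBP1 -0.39 ± 0.25 (0.583) and the water channel AQP4 -0.33 ± 0.14 (0.417). STAT3 had -0.06 ± 0.16 (0.920) and SOCS3, a feedback inhibitor of its pathway, -0.56 ± 0.32 (0.542). In the reactive gliosis list, 1 of 19 tested genes rose, or 8 when adjusted over the list alone, and 16 had positive values, with a median of 0.70 (camera adjusted p = 2.43e-05, and adjusted p = 0.824 with an estimated correlation). All 10 tested complement genes had positive values, 0 of them past the threshold in edgeR over all genes and 7 adjusted over the list alone (median 0.71, camera adjusted p = 2.03e-05, and adjusted p = 0.824 with an estimated correlation). Of 30 interferon genes, 0 rose and 1 fell over all genes and adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.000568, and adjusted p = 0.824 with an estimated correlation). The rod phototransduction list had 19 of 20 negative values in these cells, 0 past the threshold in edgeR and 1 over the list alone (median -0.38, camera adjusted p = 0.00109, and adjusted p = 0.824 with an estimated correlation). Without LG5 the camera calls of the interferon and rod phototransduction lists were lost (adjusted p = 0.335 and 0.996). Free RNA of all cells was estimated at 42.2% and 41.6% of their UMIs in LG5 and between 9.51% and 18.1% in RC726 and RC724. The estimate is the share of rod marker genes in the class divided by their share in the whole punch.

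Among genes that mark dorsal or ventral retina, 3 of 5 dorsal genes had negative values and 3 of 4 ventral genes positive values in Müller glia-like cells, 0 of them past the threshold in edgeR. TBX5, a dorsal transcription factor, had a log2 change of -2.73 ± 0.48 (SE, n = 3 pairs, edgeR adjusted p = 0.0814), and VAX2, a ventral one, 2.91 ± 0.95 (0.284). ALDH1A3, a ventral retinoic acid enzyme, had 1.32 ± 0.28 (0.126), while the dorsal genes TBX2 and TBX3 had 0.17 ± 0.14 and 0.57 ± 0.42. The dorsal ephrin genes EFNB1 and EFNB2 had -0.61 ± 0.15 and -0.95 ± 0.49, and the ventral ephrin receptor genes EPHB2 and EPHB3 0.57 ± 0.14 and -0.25 ± 0.25. These marker genes were chosen after the ALDH1A1 values were seen. Where in the retina each punch was taken is not given in the sources used here.

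**Figure D2:**
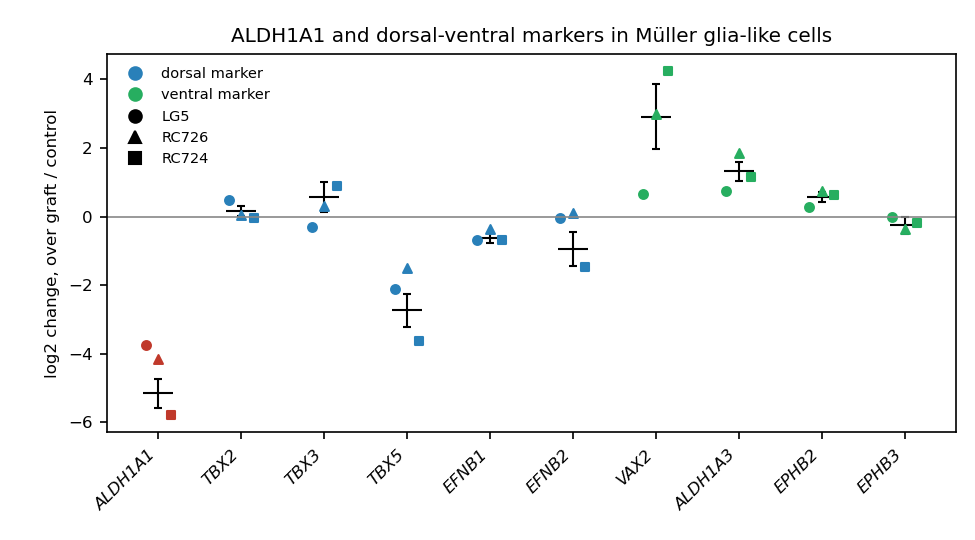
Log2 change (punch over the graft over control) of ALDH1A1 and of 5 dorsal and 4 ventral marker genes in Müller glia-like cells. Points are the 3 experiments (log2 ratio of CPM + 1) and black bars the fitted change with its SE. ALDH1A1 lies between -3.74 and -5.78, TBX5 between -1.49 and -3.64, and VAX2 between 0.67 and 4.24.

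edgeR with the block called 24 of 16328 genes in Müller glia-like cells, 18 higher and 6 lower, all 24 with one direction in the 3 experiments, and DESeq2 called 284. Without the block edgeR called 0 (143 at an unadjusted p under 0.05), and after subtraction of free RNA 0 (1211 at an unadjusted p under 0.05), while leaving out LG5, RC726 or RC724 gave 229, 2 and 59.

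The change over the graft of 12 of 31 tested interferon genes and of 7 of 14 MHC class I genes differed between Müller glia-like and rod-like cells. These counts come from the edgeR interaction fit with a term per library, which recovered 0% of simulated genes at a log2 of 2. With a class-by-experiment term, chosen after the data were seen, 23 interferon and 14 MHC class I genes were called. The lists as a whole were not tested for this difference. The change of IFI44L was 5.63 ± 0.57 log2 units smaller in Müller glia (difference -5.63, SE, n = 3 pairs, edgeR adjusted p = 0.0240), that of IRF7 differed by -4.80 ± 0.50 and that of IFI35 by -4.64 ± 0.45. For OAS1 the difference was -5.50 ± 0.60. Among MHC class I genes, B2M differed by -4.20 ± 0.48, TAPBP, a part of the peptide-loading complex, by -3.51 ± 0.40, DLA-12 by -2.73 ± 0.29 and ERAP1, a peptidase that trims MHC class I peptides, by -2.76 ± 0.33. Levels over the graft were not lower in Müller glia for all of these genes, since the control levels differed. B2M stood at 65.3 CPM in Müller glia and 2.75 CPM in rods of control punches, and at 72.0 and 57.9 CPM over the graft. Summed over 35 genes of the interferon list, Müller glia-like cells held 1397 ± 298 CPM (SD, n = 3) in control and 1234 ± 427 CPM over the graft, and rod-like cells 285 ± 25.3 and 2807 ± 2268 CPM. IFI6 alone made up 744 CPM of the Müller glia sum in control and 268 CPM over the graft, while 25 of the 30 tested genes had positive values there. S100A10, an annexin partner, was the 1 gene with a larger change in Müller glia (1.92 ± 0.23).

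**Figure D3:**
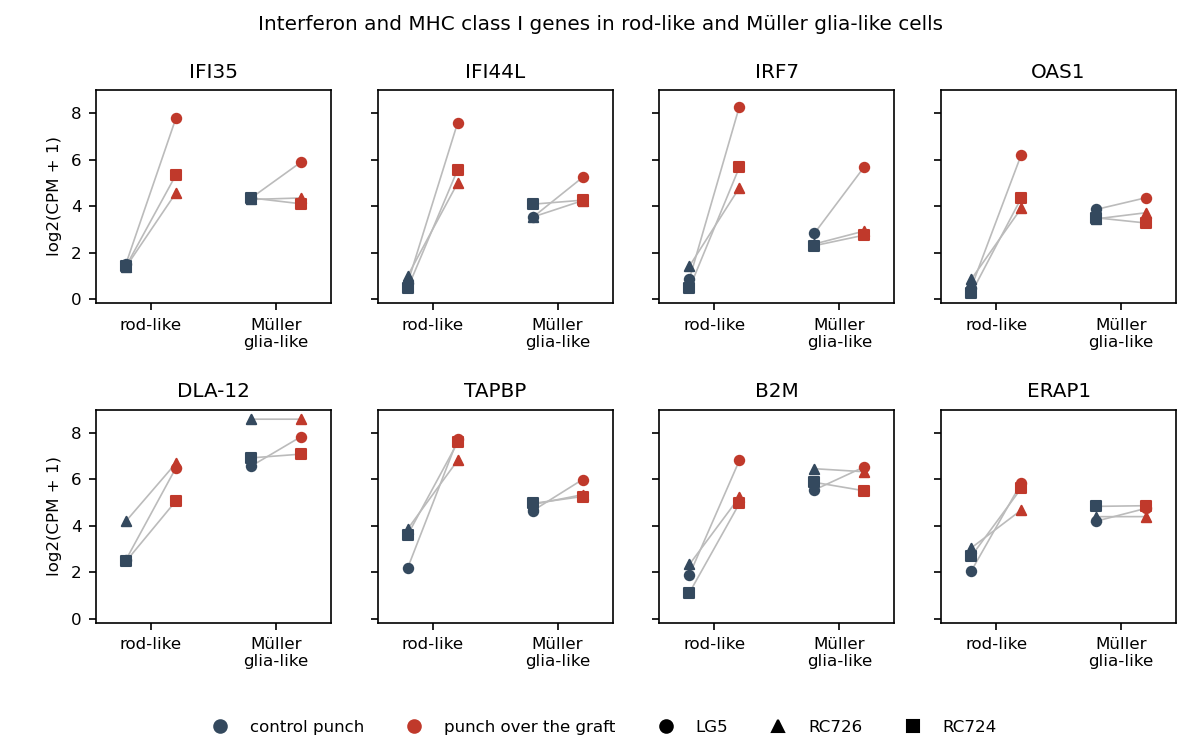
Level of 4 interferon genes (upper panels) and 4 MHC class I genes (lower panels) in rod-like and Müller glia-like cells, as log2(CPM + 1). Points are libraries, joined within an experiment from the control punch (left) to the punch over the graft (right). In rod-like cells every line goes up, as for IRF7 from a mean of 1.02 to 124 CPM, while Müller glia-like cells start higher in control, as for B2M at 65.3 CPM.

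The edgeR interaction test called 39 of 18085 genes, 1 with a larger and 38 with a smaller change in Müller glia, 12 of the 39 in the interferon list and 7 in the MHC class I list. With a class-by-experiment term, chosen after the data were seen, it called 1711, and all 39 genes were among them. Without the block it called 1 gene, after subtraction of free RNA 0 (949 at an unadjusted p under 0.05), and without LG5, RC726 or RC724 it called 61, 0 (539) and 0 (399).

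In cone-like cells, genes of the interferon and MHC class I lists were higher over the graft, and ARR3, GRK7 and GUCA1A lower. PSMB8, an immunoproteasome subunit, rose by 6.42 ± 0.58 on the log2 scale (SE, n = 3 pairs, edgeR adjusted p = 0.000116), ISG15 by 5.73 ± 0.44, TAP1 by 3.81 ± 0.60, DLA-64 by 2.35 ± 0.35 and IRF9, a part of the interferon-activated transcription complex, by 2.27 ± 0.36. VMO1 rose by 6.84 ± 0.31, to 680 CPM, and SMOC2, a matrix protein, and AQP3, a water and glycerol channel, by 5.69 ± 0.42 and 4.49 ± 0.30. ARR3, the cone arrestin, fell from 4091 to 1760 CPM (-1.504 ± 0.27), GRK7, the cone opsin kinase, by 0.81 ± 0.18 and GUCA1A by 1.39 ± 0.28, while GUCA1C, another cyclase activator, rose by 1.57 ± 0.21. ATOH7, a transcription factor of retinal progenitors, rose by 2.53 ± 0.30 and CPLX3 by 1.65 ± 0.15. THY1, S100A6 and STAT3 rose by 4.097 ± 0.33, 2.26 ± 0.30 and 1.03 ± 0.15, while STXBP4 and PLA2R1 had falls of -2.04 ± 0.33 and -1.64 ± 0.30. LG5 carried the largest part of the interferon rise: the log2 ratios of PSMB8 were 6.91 in LG5, 2.56 in RC726 and 1.21 in RC724, and those of ISG15 6.02, 2.14 and 3.02. Free RNA in the cone-like cells of LG5 was set to the upper limit of 90%. Rod marker genes held a larger share there than in the whole punch (0.685% against 0.539% over the graft, 1.354% against 1.27% in control). At this limit the subtraction cannot tell free RNA from RNA of the cone-like cells.

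Of 13 tested MHC class I genes, 8 rose in cone-like cells, or 12 when adjusted over the list alone (median 2.03, camera adjusted p = 2.16e-08), and of 12 interferon genes 8 rose, or 10 over the list alone (median 1.67, camera adjusted p = 6.50e-06). Of 13 cone phototransduction genes 1 rose and 2 fell, or 1 and 7 adjusted over the list alone (median -0.47, camera adjusted p = 0.00245, and 0.138 without LG5). The rod phototransduction list, which can reach cone droplets as free RNA, had 8 of 20 genes falling, or 15 over the list alone (median -0.67, camera adjusted p = 5.87e-11). For each of these 4 lists camera gave an adjusted p = 0.707 with an estimated correlation. edgeR called 390 of 11670 genes, 259 higher and 131 lower. Without the block it called 0 (211 at an unadjusted p under 0.05) and after subtraction of free RNA 0 (447), and leaving out RC726 or RC724 gave 718 and 127.

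In bipolar-like cells MX1, IRF7, IRF1 and PSMB8 were higher over the graft, as were CFB, C3, VIM and SLC1A3. MX1 rose by 4.78 ± 0.46 (SE, n = 3 pairs, edgeR adjusted p = 0.00302), IRF7 by 3.90 ± 0.47, IRF1, another interferon regulatory factor, by 4.29 ± 0.59 and PSMB8 by 5.53 ± 0.63. VMO1 rose by 7.17 ± 0.45 and FABP5 by 2.73 ± 0.16. CLU (clusterin) rose by 2.05 ± 0.23, and the complement genes CFB and C3 by 2.80 ± 0.32 and 2.63 ± 0.43. VIM went from 175 to 469 CPM (1.61 ± 0.22) and SLC1A3, a glial glutamate transporter, rose by 2.14 ± 0.34. S100A6, CEBPD, CRYAB and MT2A rose by 2.98, 2.11, 1.71 and 1.81, and the immediate early genes FOS and JUNB by 1.05 ± 0.13 and 1.21 ± 0.15. ALDH1A1 fell from 20.5 to 0.635 CPM (-4.95 ± 0.29), PLA2R1 by 2.16 ± 0.23 and H2AC20 by 1.23 ± 0.15. The log2 ratios of MX1 were 5.03 in LG5, 1.93 in RC726 and 1.85 in RC724, and those of PSMB8 5.88, 1.52 and 1.40, so the mean levels mostly reflect LG5. Free RNA in the bipolar-like cells of LG5 was set to the upper limit of 90% over the graft and estimated at 51.3% in control. Over the graft, rod marker genes held 0.543% of their UMIs against 0.539% in the whole punch. At this limit the subtraction cannot tell free RNA from RNA of the bipolar-like cells.

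In bipolar-like cells 5 of 8 complement genes rose (6 adjusted over the list alone, median 1.83, camera adjusted p = 1.32e-07), and 6 of 12 reactive gliosis genes (9 over the list alone, median 1.47, camera adjusted p = 1.32e-07). Of 15 interferon genes 2 rose, or 11 over the list alone (median 1.48, camera adjusted p = 4.55e-07). With an estimated correlation these 3 lists had adjusted p = 0.40, adjusted p = 0.439 and adjusted p = 0.507. In the Müller glia homeostasis list 9 of 12 tested genes had positive values, 1 of them past the threshold over all genes and over the list alone (camera adjusted p = 0.0090, and adjusted p = 0.567 with an estimated correlation). This camera call was lost without RC726 (adjusted p = 0.0640) and without RC724 (0.231). VIM stood at 16113 CPM in Müller glia-like cells over the graft. edgeR called 112 of 13914 genes, 99 higher and 13 lower. Without the block it called 0 (122 at an unadjusted p under 0.05), after subtraction of free RNA 0 (228), and without LG5 390. In RC724, different clusters held most of this class: cluster 16 had 430 barcodes over the graft and 0 in control, and cluster 21 had 51 and 783.

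Amacrine-like cells rested on 24 to 36 barcodes per library in RC726 and RC724. In them UBE2L6, an enzyme of ISG15 conjugation, rose by 1.88 ± 0.31 (SE, n = 3 pairs, edgeR adjusted p = 8.61e-05) and RNF213 by 1.59 ± 0.32. VMO1 rose by 7.04 ± 0.46 from 4 UMIs in all control amacrine-like cells to 1112 UMIs over the graft. APOC1, an apolipoprotein, and FABP5 rose by 1.57 ± 0.25 and 1.61 ± 0.29 and MT2A by 1.03 ± 0.25. SCG2, a secretory granule protein, NRG1, a growth factor, and SLC17A8, a vesicular glutamate transporter, fell by 1.42 ± 0.31, 1.38 ± 0.29 and 1.22 ± 0.22. IMPG2, which photoreceptors express, rose by 1.42 ± 0.26 in these cells, and 11 of 12 genes of the outer segment list had positive values, 2 of them rising over all genes and 6 over the list alone (camera adjusted p = 1.87e-07, and adjusted p = 0.548 with an estimated correlation). Free RNA in amacrine-like cells was estimated at 41.4% over the graft and 18.5% in control in LG5, 21.4% and 11.8% in RC726, and 40.0% and 22.3% in RC724. Horizontal-like cells had 2 genes past the threshold, FABP5 (2.43 ± 0.32, edgeR adjusted p = 0.0153) and APOC1 (1.95 ± 0.24, 0.0153). The next smallest p in horizontal-like cells belonged to PDE6G (1.39 ± 0.22, adjusted p = 0.0779), C7H1orf21 (-1.80 ± 0.30, 0.0953) and NGFR (-1.39 ± 0.28, 0.352). edgeR called 39 of 5550 genes in amacrine-like cells, 29 higher and 10 lower, and 2 of 6059 in horizontal-like cells. Without the block it called 0 in both (14 and 32 at an unadjusted p under 0.05), and in amacrine-like cells DESeq2 called 14, the subtraction of free RNA left 0 (163), and leaving out LG5 or RC726 gave 14 and 64. Leaving out LG5, RC726 or RC724 gave 52, 0 (388 at an unadjusted p under 0.05) and 45 in horizontal-like cells.

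Microglia- or macrophage-like cells had fewer than 20 barcodes in both the RC726 and the RC724 control, so this class missed the minimum set for a test and its fit was added without that minimum. FBP1, a gluconeogenic enzyme of macrophages, went from 66.2 to 638 CPM (2.92 ± 0.67, SE, n = 3 pairs, edgeR adjusted p = 0.0139), and CTSB, a lysosomal protease, from 51.3 to 444 CPM (2.72 ± 0.68, 0.0396). GLIPR2 rose by 3.51 ± 0.83, from 6 UMIs in all control cells to 351 UMIs over the graft, and RPS29 fell by 1.09 ± 0.27. LOC119877774 and LOC119877775, for which no name was matched, fell by 1.68 ± 0.16 and 1.86 ± 0.18. The barcodes of this class were split unevenly between clusters. In LG5, cluster 38, with FBP1 among its top 10 genes, held 174 barcodes over the graft and 5 in control, cluster 49 held 110 and 2, and cluster 62 held 45 and 5. The microglial receptors CX3CR1 and P2RY12 had log2 changes of -0.30 ± 0.59 and -0.63 ± 0.59, the phagocyte genes AIF1, CD74 and C1QA 0.19 ± 0.46, 0.56 ± 0.35 and 0.37 ± 0.29, and SPP1, osteopontin, 0.59 ± 0.46, each with an edgeR adjusted p = 0.997. edgeR called 6 of 3395 genes, 3 higher and 3 lower, and DESeq2 called 0 (287 at an unadjusted p under 0.05). Without the block edgeR called 0 (70), and without LG5 it called 1. After subtraction of free RNA it called 2, 0 of them higher, and the log2 changes of FBP1, CTSB and GLIPR2 were then 2.98, 2.77 and 3.67 with adjusted p = 0.0872, 0.199 and 0.0872. The stricter barcode filter also left 2 calls, 0 of them higher. Free RNA in this class was estimated at 9.86% over the graft and 68.7% in control in RC724, 16.6% and 15.0% in LG5, and 10.5% and 6.88% in RC726.

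In the sum over all retained barcodes of a punch, GFAP, TIMP1, CCL2 and interferon genes were higher over the graft, and ARR3, GUCA1A and ALDH1A1 lower. GFAP rose by 2.02 ± 0.16 (SE, n = 3 pairs, edgeR adjusted p = 0.0111), NES by 1.55 ± 0.18 and TIMP1, an inhibitor of matrix proteases, from 147 to 1495 CPM (2.67 ± 0.53). CCL2, a monocyte attractant, rose by 2.44 ± 0.27, CSF1, a macrophage growth factor, by 1.33 ± 0.15, CFB by 1.35 ± 0.15 and FN1, fibronectin, by 2.88 ± 0.51. IRF7, USP18 and TAPBP rose by 3.26, 1.59 and 1.89, while IFI6 fell by 1.19 ± 0.13. VMO1 and AQP3 rose by 5.56 ± 0.69 and 4.61 ± 0.57. ALDH1A1 fell by 4.29 ± 0.53, PLA2R1 by 2.18 ± 0.31, ARR3 by 1.87 ± 0.29 and GUCA1A by 1.55 ± 0.24. Of 35 interferon genes 16 rose and 1 fell, or 31 and 1 adjusted over the list alone (median 1.26, camera adjusted p = 1.60e-13, and adjusted p = 0.419 with an estimated correlation). Of 21 reactive gliosis genes 5 rose, or 11 over the list alone (camera adjusted p = 2.44e-07), and of 20 rod phototransduction genes 10 fell, or 18 over the list alone (camera adjusted p = 5.08e-12), each with an adjusted p = 0.419 with an estimated correlation. Of 20 cytokine and chemokine genes 5 rose, or 10 over the list alone (camera adjusted p = 1.46e-06, and adjusted p = 0.417 with an estimated correlation).

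These sums mix changes within cells with changes in the share of each class. edgeR called 794 of 21433 genes in the whole punch, 463 higher and 331 lower, and DESeq2 called 2011. Without the block edgeR called 0 (343 at an unadjusted p under 0.05), and without RC726 466. Across the gene lists, camera called 13 of 30 lists in rod-like cells, 13 of 31 in Müller glia, 9 of 28 in cones, 17 of 28 in bipolar cells and 24 of 31 in the whole punch. With an estimated correlation 0 lists were called by camera in any class, while fry's directional test, which asks whether a list's genes move on balance one way, called 4 in rods and 3 in bipolar cells. The 4 in rods did not include the interferon, MHC class I, rod phototransduction and oxidative stress lists (fry adjusted p = 0.115, 0.0577, 0.115 and 0.108), and the 3 in bipolar cells included the complement list (0.0123) but neither the interferon nor the reactive gliosis list (0.263 and 0.139). All 13 mitochondrially encoded genes had negative values in Müller glia, cones, bipolar and amacrine cells. In cones, bipolar and amacrine cells 2, 2 and 1 of them fell, or 3, 2 and 3 adjusted over the list alone (camera adjusted p = 0.000884, 0.000516 and 0.00698, and adjusted p = 0.707, 0.507 and 0.648 with an estimated correlation). In Müller glia 2 of them fell when adjusted over the list alone and edgeR called 0 over all genes (camera adjusted p = 0.000104, and adjusted p = 0.824 with an estimated correlation). Without LG5 the camera call was lost in cones, bipolar and amacrine cells (adjusted p = 0.346, 0.587 and 0.359) and stayed in Müller glia (0.0158). In rods 8 of the 13 had positive values and 1 fell, over all genes and over the list alone (camera adjusted p = 0.830, and adjusted p = 0.9502 with an estimated correlation).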

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

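The tests of RNA from other cells, of depth, of dilution and of other splits of the libraries were chosen after the results were seen. The tests of dorsal-ventral position and of rod clusters were written before their own values were computed, and after the patterns they address had been seen.

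A difference between cell classes was seen for 39 genes, whose change over the graft differed between Müller glia-like and rod-like cells in the edgeR interaction test. The differences on the log2 scale were -5.63 for IFI44L, -5.50 for OAS1, -4.80 for IRF7, -4.64 for IFI35, -4.20 for B2M, -3.51 for TAPBP, -2.76 for ERAP1, -2.73 for DLA-12 and 1.92 for S100A10. In the split of the 6 libraries by group, 1 of 10 splits gave as many genes, the real one, with 0 as the highest other count. That is too few splits for a share under 0.05.

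T or NK cell-like barcodes, a class outside the comparisons, made up 0.717% (161 of 22458; 95% interval 0.611% to 0.836%) of the LG5 punch over the graft and 0.0237% (4 of 16844) of its control. Under the stricter barcode filter the LG5 shares were 0.391% (72 of 18417) and 0.0087% (1 of 11429). Under the main filter they were 4 of 10640 and 0 of 9314 barcodes in RC726, and 2 of 8701 and 3 of 8079 in RC724.

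The first pattern weighed is the rise of interferon and MHC class I genes in rod-like cells. If RNA of microglia or macrophages in rod droplets were the source, their markers would stand near the level that the needed share brings, and they reached at most 0.63% of it. Markers of Müller glia reached at most 2.81% of the level needed from those cells. A difference in depth also falls short, since 82.6% of the interferon genes that rose (19 of 23) were still past the threshold after thinning. RNA of other cell classes or of the graft was not tested as a source and stays open. A response of rods to the graft, to the surgery or to a difference between retinal areas may remain, as a hypothesis that these punches cannot divide, because no punch over a sham injection is among the libraries.

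The second pattern is the low ALDH1A1 of Müller glia-like cells over the graft. If the punches lay at different dorsal-ventral positions, ventral markers would gain on dorsal markers, and they did so by 1.66 log2 units on average (0.94 in LG5, 1.58 in RC726 and 2.44 in RC724, SD 0.754). A position difference may therefore account for the ALDH1A1 values, and a response to the graft that moves the same markers stays open. A position difference also stays open for every other comparison of the 2 punches, as each experiment has 1 punch per area.

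The third pattern is the fall of phototransduction genes in rod-like cells. A shift between rod clusters would leave the list near 0 within clusters, while its median log2 change within clusters was -0.75 (SD 0.271 over 14 pairs of cluster and experiment, 14 of them below -0.2). Dilution by RNA of Müller glia, bipolar, amacrine or cone cells would raise their markers in the rod sums. Over 52 such markers the gain was at most 2.43% of what is needed. RNA of other cell classes or of the graft was not tested as a source of dilution and stays open. Loss of these transcripts in rods, or a difference between retinal areas, may remain as a hypothesis.

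For the other counts, the 10 splits of 6 libraries are likewise too few for a share under 0.05. The real split gave 3184 genes in rods, 24 in Müller glia, 390 in cones and 794 in the whole punch, each with 0 as the highest other count, and was the 1 split as large. It gave 112 genes in bipolar cells against 2, 39 in amacrine cells against 4 and 6 in microglia against 4. In horizontal cells 4 of the 10 splits gave at least 2 genes, with 18 as the highest other. Over all classes the real split called 95 lists and 3 of the 10 splits called as many, with 96 as the highest. Among the 4 splits that part all 3 pairs, the highest other counts were 0 in rods, Müller glia, cones, bipolar cells and the whole punch, 4 in amacrine cells, 5 in horizontal cells, 4 in microglia and 66 lists. The 96 lists came from 2 splits that each part 1 pair, that of LG5, and gave the same counts in every class. With the experiment as a block, the group term of such a split rests on that pair alone. Here it compares the LG5 punch over the graft with its control. These 2 splits therefore do not show how many lists are called without a difference between punches. The other splits that part 1 pair also gave the same counts 2 by 2.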

How the results depend on the processing

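Of the alternatives tried, the class-by-experiment term, the rod fit without clusters lacking a rod marker in their top 10 genes, and all fits of microglia- or macrophage-like and of horizontal-like cells were chosen after the data were seen. Of 175 named genes, 147 were past the threshold, and of 1824 values under alternatives 1816 kept their direction. On their side of the threshold 1472 stayed, 311 lost the call, 33 gained it and 8 reversed, 0 of these among called genes. A further 50 values could not be had, as the gene was not tested or had no adjusted p. The causes were not tested except where fewer genes or experiments enter a fit.

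Without the replicate block (the pairing), edgeR called 0 genes in rods, Müller glia, cones, bipolar, amacrine, horizontal cells, microglia and the whole punch, with 671, 143, 211, 122, 14, 32, 70 and 343 at an unadjusted p under 0.05, and 1 gene in the interaction. Without the block camera called 1 list in horizontal cells and 5 in microglia, and list counts elsewhere stayed within 1.5 times.

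DESeq2 called 284 genes in Müller glia (150 higher, 134 lower), 14 in amacrine cells (12 and 2), 4 in horizontal cells, 0 in microglia (287 at an unadjusted p under 0.05) and 2011 in the whole punch, and 150 in bipolar cells (114 and 36). Without the filter on low counts edgeR called 970 genes in Müller glia, 963 in cones, 1080 in bipolar, 84 in amacrine and 88 in horizontal cells, 13 in microglia, 1951 in the whole punch and 175 in the interaction. The stricter barcode filter gave 62 in Müller glia, 24 in amacrine cells, 4 in horizontal cells and 2 in microglia. Thinning gave 42 in Müller glia, 5 in amacrine cells and 0 in microglia (9 at an unadjusted p under 0.05, of 140 tested). After subtraction of free RNA edgeR called 0 in Müller glia (1211 at an unadjusted p under 0.05), cones (447), bipolar (228) and amacrine cells (163) and in the interaction (949), and 2 in microglia. The class-by-experiment term gave 1711, and the rod fit without clusters lacking a rod marker 2932. Doublets kept and RLE factors moved no gene count by over 1.5 times.

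With 1 experiment left out, counts ranged from 997 to 2780 genes in rods, 2 to 229 in Müller glia, 127 to 718 in cones, 113 to 390 in bipolar, 14 to 64 in amacrine and 0 to 52 in horizontal cells, 1 to 8 in microglia, 466 to 871 in the whole punch and 0 to 61 in the interaction. Lists ranged from 10 to 18 in rods, 12 to 15 in Müller glia, 6 to 10 in cones, 15 to 19 in bipolar, 2 to 8 in amacrine and 7 to 9 in horizontal cells, 4 to 9 in microglia and 22 to 24 in the whole punch. The Müller glia share ranged from -0.0677 to 0.31 (the lowest without RC726), the bipolar share from -0.39 to 0.15 and the ganglion share from -1.44 to 0.0152 (the highest of both without RC724). STAT3 in Müller glia ranged from -0.18 to 0.10 (the highest without RC724), TBX3 from -0.0202 to 1.25 (the lowest without RC724) and EFNB2 from -1.70 to 0.0857 (the highest without RC724). In microglia, CX3CR1 ranged from -0.78 to 0.32 and P2RY12 from -0.66 to 0.54 (the highest without LG5), CD74 from -0.042 to 1.15, C1QA from -0.0357 to 0.70 and SPP1 from -0.60 to 2.52 (the lowest without RC724).

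Camera with an estimated correlation called 0 lists in rods, Müller glia, cones, bipolar, amacrine, horizontal cells, microglia and the whole punch. The directional fry test called 4 in rods, 3 in bipolar cells and 0 in Müller glia, cones, amacrine, horizontal cells, microglia and the whole punch, and the mixed fry test 20 in rods, 6 in Müller glia, 13 in bipolar cells, 11 in the whole punch and 0 in cones, amacrine, horizontal cells and microglia. In microglia, simulated genes changed by a log2 of 1 were recovered at 4.55%.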

Other observations

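The tests and genes of this part beyond the naming rule were chosen after the values were seen.

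Rod-like cells over the graft also had more RNA of LPL, FABP5, FGF1 and HK2. LPL, a lipase, rose from 1.22 to 27.9 CPM (log2 change 4.35 ± 0.24, SE, n = 3 pairs, edgeR adjusted p = 5.94e-06), FABP5 by 2.33 ± 0.23 and FGF1, a growth factor, from 16.4 to 54.3 CPM (1.69 ± 0.14). HK2 and LDHA, enzymes of glycolysis, rose by 1.12 ± 0.15 and 1.16 ± 0.18, TRIB3, a gene of the integrated stress response, by 1.55 ± 0.18, and GFAP by 1.78 ± 0.22, to 10.5 CPM. All of these were higher over the graft in 3 of 3 experiments. GFAP had 313 UMIs in rod-like cells over the graft and 74 in control, against 8711 and 1675 in Müller glia-like cells. Free RNA was not estimated for rod-like cells, so glial RNA in rod droplets was not tested as the source of this GFAP. FGF2, another growth factor, fell (-1.01 ± 0.25, edgeR adjusted p = 0.0153). Of 25 genes of the glycolysis and hypoxia list 9 rose and 3 fell, or 11 and 4 over the list alone, and of 12 neurotrophic factors 3 rose and 2 fell, or 5 and 2 over the list alone. Camera called neither list (adjusted p = 0.122, and adjusted p = 0.544 with an estimated correlation, for the first, and adjusted p = 0.148, and adjusted p = 0.46 with an estimated correlation, for the second).

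SREBF2, the transcription factor of cholesterol genes, rose by 1.17 ± 0.20 (SE, n = 3 pairs) in rod-like cells and by 1.202 ± 0.23 in cone-like cells. In Müller glia-like cells all 20 genes of the cholesterol synthesis list had positive values, 0 past the threshold in edgeR over all genes and 7 adjusted over the list alone (median 0.64, camera adjusted p = 7.29e-07, and adjusted p = 0.824 with an estimated correlation). In rod-like cells 3 of the 20 rose and 2 fell, or 4 and 2 over the list alone (camera adjusted p = 0.532). The difference between the classes was not tested for this list.

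In microglia- or macrophage-like cells all 12 tested genes of the cell cycle list had positive values, 0 past the threshold in edgeR over all genes and 7 adjusted over the list alone (median 1.501, camera adjusted p = 6.81e-06, and adjusted p = 0.695 with an estimated correlation). This class missed the minimum of cells set for a test. The RC724 control held 10 barcodes with 9683 UMIs, 68.7% of them estimated as free RNA, against 228721 UMIs over the graft. Without RC724 the camera call stayed (adjusted p = 1.67e-08). Cluster 62, with UBE2C among its top 10 genes, held 45 barcodes over the graft and 5 in control in LG5. It held 3 and 0 in both RC726 and RC724. A shift between clusters was not tested as the source of the list values. TOP2A, a topoisomerase of dividing cells, rose by 3.19 ± 0.41 in the whole punch, from 0.385 to 3.58 CPM (edgeR adjusted p = 0.0199). Which cell class carried this rise was not tested.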
